A study of Homo sapiens with 6 samples.

How the data were processed

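Messenger RNA levels were measured by RNA sequencing in mesenchymal stem cells derived from the H9 human embryonic stem cell line. The design held 6 libraries, 3 from untreated cells and 3 from cells kept in medium with 200 µM melatonin for 24 h. Per the labels' protocols, 1.3 µg of column-purified total RNA entered each directional library. The deposited files give whole-number counts per gene symbol, with no normalization, for 1 library each. Per the submitters' processing notes, TopHat was used with the human genome build hg19. The version of TopHat, the program that counted reads, its strand setting, the gene annotation and any filter are not given in the sources used here. The files carry gene symbols and no coordinates, and no hg19 annotation was used here, so genomic positions are not stated.

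How reads were counted could affect the values in several ways. A counter that splits or drops reads shared between overlapping genes, gene families or pseudogenes changes the counts of read-through symbols, histone genes, FTH1, FTL, HSPA1A, HSPA1B and members of the GSTM family, so these counts are uncertain. Without a stated strand setting, reads of a gene and of its antisense partner may not have been told apart. The files held 24424 symbols, of which 5620 had no count in any library. None of the fixed symbols of mitochondrially encoded genes matched, so that list and the share of mitochondrial RNA were not analysed here.

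From the counts, counts relative to library size (normalized CPM) were computed with edgeR 4.0.16 in R 4.3.3, using library sizes scaled by the trimmed mean of M-values (TMM). Genes were kept by filterByExpr, which left 13455. Melatonin-treated and untreated libraries were compared by edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A log2 fold change is melatonin over untreated. Its standard error (SE) is the unshrunk coefficient divided by the square root of the F statistic. Means are given with the standard deviation (SD) over 3 libraries.

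Before the data were examined, the groups, the test, the alternatives, 47 gene lists and the rule for named genes were fixed. The lists held 36 tested pathway lists, 9 tested lists of cell type markers, and 2 that could not be tested, those of mitochondrially encoded genes and of haematopoietic markers. Lists with at least 3 tested members were compared with all other genes by camera in limma 3.58.1 on log2 CPM with a prior count of 2, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 45 lists tested. Camera with an estimated correlation was an alternative. So was fry, which asks whether the genes of a list move, on balance, in 1 direction and does not compare the list with other genes. The named genes were the 10 with the largest rise and the 10 with the largest fall among genes past the threshold, with mean log2 CPM of at least 1 and no overlap between the groups. Up to 3 members with the smallest p were added from each list past the threshold, and 16 genes of glutathione and melatonin biology were named whatever their value. Any other list member or gene that the text names was chosen after its values were seen. A few genes that the rule takes are not reported here.

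The total count per library ran from 18688409 to 24452599. A count of 0 allows up to 3 counts, which is 0.123 to 0.161 CPM depending on the library, and this floor covers counting error only. The test was tested on simulated data, with counts drawn for the same 13455 genes from their means and the library sizes. All genes had 1 common biological coefficient of variation, 4.03%, in both groups, and 200 genes were changed when the test was run. The test called 76.0% of genes changed 1.25-fold, 86.0% of those changed 1.5-fold, 94.0% of those changed 2-fold and all of those changed 4-fold. Unchanged genes made up 7.29% of its calls. Camera called 10 of 10 shifted lists and 0 of 100 lists with no shift. In that simulation genes varied independently, so it does not test how camera behaves with correlated genes. In the data the common coefficient of variation was 3.04% within untreated and 4.90% within melatonin libraries, and 4765 genes were called. The simulated rates therefore may not hold for these data.

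Alternatives were the median-of-ratios scaling and Wald test of DESeq2 1.42.0, scaling by total counts only, limma-voom, no filter beyond 1 count, a minimum of 10 counts in every library, leaving out the 20 most abundant genes, leaving out each library in turn, and fits with a library number as a block. Thinning of every library to the smallest total, and removal of per-library trends on GC content and transcript length, were added after the data were examined. Transcript GC content and length came from GENCODE transcripts of another human build and matched 94.6% of the genes tested. Each library was also compared with every other by a chi-square test over genes with at least 20 counts in the pair. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.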

Results

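The data set held 6 RNA sequencing libraries from mesenchymal stem cells that had been derived from H9 human embryonic stem cells and grown in endothelial cell medium on rat-tail collagen. Untreated cells gave 3 libraries, with total counts of 24452599, 24246821 and 23955201. Cells primed for 24 h with 200 µM melatonin, a pineal hormone with antioxidant activity, gave 3 libraries with total counts of 18688409, 19226357 and 23143928. Every pair of libraries from the same group differed by more than sampling noise, with a chi-square per degree of freedom of 2.20 to 5.78, against 20.7 to 28.0 between groups. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The first principal component held 52.2% of the variance and separated the groups. On the second component (15.2%) melatonin library 1 lay at 20.7, against -12.5 and -5.32 for the other melatonin libraries and -2.96 to 1.77 for the untreated libraries.

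The comparison asked which transcripts differed between melatonin-primed and untreated cells, with glutathione metabolism named by the study as its subject. With melatonin, 18 of 25 measured NRF2 targets rose, as did 11 of 18 glutathione peroxidases and transferases, 11 of 21 fatty acid and lipid droplet genes and 10 of 27 genes of autophagy and the lysosome. Of the measured genes of mitosis, DNA replication and ribosome biogenesis, 29 of 32, 26 of 30 and 26 of 28 fell, with list medians of -0.29 to -0.32 on the log2 scale, and several genes of the contractile cytoskeleton, the simple epithelial keratins and part of the extracellular matrix fell further. As lists these groups passed camera with a preset correlation and did not pass with an estimated one (adjusted p = 0.199 to 0.539 with an estimated correlation). The largest fall among named genes was that of NPPB, which encodes the precursor of B-type natriuretic peptide, from 5.32 ± 1.18 to 0.429 ± 0.162 CPM (SD, n = 3 in each group). Among the named genes that rose, ID4, an inhibitor of basic helix-loop-helix factors, went from 2.18 ± 0.172 to 6.54 ± 0.475 CPM (SD, n = 3 in each group).

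Of 13455 genes tested, 2197 rose and 2568 fell. Most changes were small. The median change of the 4765 genes was 1.22-fold, and 254 of them (112 higher, 142 lower) changed at least 2-fold. The libraries of the 2 groups did not overlap for 4526 of the changed genes. Among all tested genes they did not overlap for 45.6%, against 10% given by chance for 3 libraries against 3. The split between directions depended on scaling. With total counts only, 3440 genes were higher and 1739 lower, so that 66.4% of calls were higher instead of 46.1%. Of 45 tested gene lists, camera called 4 higher and 8 lower, and 33 did not pass. With an estimated correlation none of the 45 passed, 9 had an unadjusted p under 0.05, and the smallest adjusted p was 0.199. This version takes its degrees of freedom from the 6 libraries instead of the number of genes, so lists pass it less readily. Epithelial markers lost their call although their estimated correlation (-0.01) lay below the preset 0.01, with unadjusted camera p of 2.90e-04 and 0.0194. G2 and mitosis had an estimate of 0.22. A loss under this version therefore does not by itself show correlated members. By fry, 25 lists passed.

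NRF2 is a transcription factor that induces detoxifying and antioxidant enzymes. Of 25 measured NRF2 targets, 18 rose and 1 fell, and the same counts were obtained when adjusted over the list alone. The median log2 fold change was 0.35 (camera adjusted p = 1.62e-07; adjusted p = 0.199 with an estimated correlation). SQSTM1, an autophagy receptor, rose from 253 ± 4.84 to 421 ± 11.6 CPM (SD, n = 3; log2 fold change 0.73 ± 0.04 SE). The ferritin subunits FTL and FTH1, which store iron, rose by 0.68 ± 0.04 and 0.58 ± 0.04 (SE). The quinone reductase NQO1 rose from 246 ± 2.47 to 363 ± 23.6 CPM (SD, n = 3; adjusted p = 5.28e-09). NFE2L2, which encodes NRF2, rose by 0.15 ± 0.04 (SE; adjusted p = 0.0139), a call that ended on leaving out untreated library 1 (0.0614) or 2 (0.0651) or melatonin library 2 (0.0559) or 3 (0.0727), with log2 fold changes of 0.13 to 0.14. Over all alternatives its adjusted p ran from 2.51e-04 to 0.254. HMOX1 (0.16 ± 0.12 SE) and TXNRD1 (0.07 ± 0.04 SE) did not pass, with adjusted p of 0.34 and 0.225. TXNRD1 passed without melatonin library 2 (adjusted p = 0.0499; range over alternatives 0.0209 to 0.899).

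The genes of glutathione synthesis and recycling did not pass as a list against all other genes, while fry, which makes no such comparison, called them higher. Of 23 measured members, 7 rose and 4 fell, with the same counts when adjusted over the list alone and a median log2 fold change of 0.06 (camera adjusted p = 0.255; fry adjusted p = 0.00336). The catalytic subunit of glutamate-cysteine ligase, GCLC, which carries out the rate-limiting step of glutathione synthesis, rose from 35.4 ± 1.91 to 48.0 ± 1.57 CPM (SD, n = 3; log2 fold change 0.44 ± 0.06 SE, adjusted p = 4.41e-06). Its modifier subunit GCLM rose by 0.17 ± 0.05 (SE) and glutathione reductase, GSR, by 0.20 ± 0.04 (SE). Other members that rose included the NADPH-generating enzymes PGD and IDH1 and the transaldolase TALDO1. Glutathione synthetase, GSS, did not pass (-0.09 ± 0.05 SE, adjusted p = 0.178). Both subunits of the cystine importer were lower. SLC3A2 fell by 0.25, and SLC7A11 fell by 0.13 (adjusted p = 0.0329). The SLC7A11 call ended without untreated library 2 (0.0743) or 3 (0.169), without melatonin library 2 (0.0719) or 3 (0.258), and with total counts only (0.286), with log2 fold changes of -0.07 to -0.14. Its adjusted p over all alternatives ran from 4.88e-04 to 0.286. The glutathione-degrading enzymes CHAC1 and CHAC2 also fell, by 0.23 and 0.29.

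Of 18 glutathione peroxidases and transferases, 11 rose and 1, GSTO1, fell. Adjusted over the list alone, 12 rose and 1 fell. The median was 0.26 (camera adjusted p = 0.00471; adjusted p = 0.281 with an estimated correlation). GPX4, which reduces lipid hydroperoxides, rose 1.31-fold, GSTM3 1.32-fold and GSTZ1 1.40-fold. The other antioxidant enzymes did not pass as a list, with 3 of 22 higher and 4 lower (adjusted p = 0.831), and PRDX1 did not pass (-0.04 ± 0.05 SE, adjusted p = 0.514). PRDX1 passed without melatonin library 1 (-0.09, adjusted p = 0.0388; range over alternatives 0.0388 to 0.832). CREB1 did not pass either (-0.01 ± 0.05 SE, adjusted p = 0.903).

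**Figure D1:**
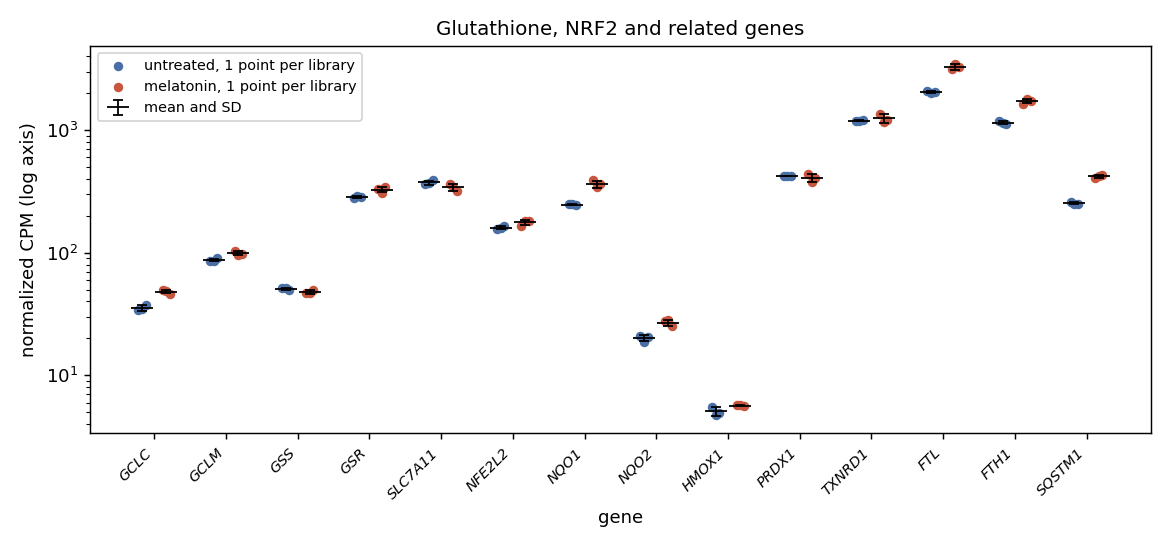
Normalized CPM on a log axis for glutathione, NRF2 and related genes, 1 point per library, with the mean and SD of 3 untreated and 3 melatonin libraries. FTL, FTH1, SQSTM1, NQO1 and GCLC lay higher in every melatonin library than in every untreated library, while the groups overlapped for SLC7A11, PRDX1 and TXNRD1.

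The melatonin receptor genes were at or below the detection floor. MTNR1A had 3 counts in untreated library 2 and 0 in the other libraries, and MTNR1B had 0 in all 6, which allows up to 0.123 to 0.161 CPM per library. Neither could be tested. Of 7 measured genes of melatonin receptors and metabolism, 3 rose and 1 fell (adjusted p = 0.582). NQO2, a quinone reductase known to bind melatonin, rose 1.34-fold to 26.9 ± 1.59 CPM (SD, n = 3; adjusted p = 8.64e-05). The melatonin-oxidizing cytochrome CYP1B1 fell by 0.55 ± 0.05 (SE; adjusted p = 1.15e-07), and CYP1A1 did not pass (-0.22 ± 0.14 SE, adjusted p = 0.261).

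Of 21 genes of fatty acid synthesis and lipid droplets, 11 rose and 3 fell. Adjusted over the list alone, 12 rose and 3 fell. The median was 0.16 (camera adjusted p = 0.00853; adjusted p = 0.199 with an estimated correlation). The members that rose most were PDK4 and ANGPTL4, neither of which is an enzyme of fat synthesis. PDK4, a kinase that blocks pyruvate oxidation, rose from 9.34 ± 0.622 to 22.1 ± 0.363 CPM (SD, n = 3). ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose 2.10-fold, and the lipid droplet coat protein PLIN2 rose 1.29-fold. The synthesis genes FASN and ACACA did not pass, and ACLY fell by 0.21. Of 27 genes of autophagy and the lysosome, 10 rose and 3 fell (10 and 4 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 0.0191; adjusted p = 0.21 with an estimated correlation). Besides SQSTM1, the autophagy kinase ULK1 rose 1.61-fold and the lysosomal sialidase NEU1 rose 1.40-fold, while ATG14, ATG7 and the proton pump subunit ATP6V1H fell.

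Of 32 genes of G2 and mitosis, 29 fell and none rose. The median was -0.32 (camera adjusted p = 3.41e-11; adjusted p = 0.213 with an estimated correlation). The cytokinesis scaffold ANLN fell from 361 ± 5.15 to 251 ± 6.87 CPM, the mitotic kinesin KIF23 from 104 ± 2.53 to 73.1 ± 4.48 CPM and the anaphase activator CDC20 from 173 ± 5.58 to 126 ± 4.23 CPM (SD, n = 3). Of 30 genes of DNA replication, 26 fell and none rose, with a median of -0.29 (camera adjusted p = 1.69e-09; adjusted p = 0.199 with an estimated correlation). Among them UHRF1, a factor of DNA methylation maintenance, fell by 0.55 and the helicase subunits MCM7 and MCM5 by 0.42 and 0.40. Of 28 genes of ribosome biogenesis and other MYC targets, 26 fell and none rose, with a median of -0.31 (camera adjusted p = 4.18e-11; adjusted p = 0.199 with an estimated correlation). The RNA helicase DDX21 fell by 0.56, and the processome components UTP20 and WDR43 fell by 0.50 and 0.41. MYC itself did not pass (-0.08, adjusted p = 0.34). Ribosomal protein genes did not pass as a list, with 4 of 37 higher and 6 lower (adjusted p = 0.585). Adjusted over the list alone, the counts in these 4 lists were the same.

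Of 24 TGF-β targets and actin cytoskeleton genes, 17 fell and 3 rose, with the same counts when adjusted over the list alone. The median was -0.51 (camera adjusted p = 3.16e-07; adjusted p = 0.199 with an estimated correlation). The actin-binding protein TAGLN fell from 148 ± 6.50 to 47.1 ± 1.57 CPM (SD, n = 3; adjusted p = 2.26e-15). ANKRD1, a muscle ankyrin repeat protein, was 2.79-fold lower, and smooth muscle γ-actin ACTG2 was 1.92-fold lower. The members that rose were ID1 (0.66), ID2 (0.45) and ID3 (0.49), inhibitors of basic helix-loop-helix factors known as targets of BMP signalling. Of 12 smooth muscle and pericyte markers, 7 fell and 2 rose (the same adjusted over the list alone), with a median of -0.42 (camera adjusted p = 0.0298; adjusted p = 0.316 with an estimated correlation). This call ended without melatonin library 1, the library that stood apart on the second component, while the median stayed at -0.37 (adjusted p = 0.103; range over fits with the preset correlation 0.00511 to 0.103). CNN1 fell from 4.27 ± 0.115 to 1.15 ± 0.289 CPM (SD, n = 3), NOTCH3 and ABCC9 rose by 0.32 and 0.31, and ACTA2 did not pass (0.17, adjusted p = 0.148). TAGLN, ACTG2, CNN1 and ACTA2 belong to both this list and that of TGF-β targets, so the results of these lists are not separate.

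Of 35 collagens and other matrix genes, 19 fell and 4 rose, and adjusted over the list alone 19 fell and 5 rose. The median was -0.15 (camera adjusted p = 0.00504; adjusted p = 0.539 with an estimated correlation). TNC, a matrix glycoprotein of remodelling tissue, fell from 1424 ± 37.4 to 676 ± 39.3 CPM, THBS1 from 1559 ± 64.3 to 946 ± 13.2 CPM and COL12A1 from 809 ± 37.3 to 489.6 ± 21.2 CPM (SD, n = 3). The members that rose were LUM (0.35), FBLN1 (0.19), NID1 (0.16) and FN1 (0.13), and COL3A1 did not pass (-0.03, adjusted p = 0.447). Of 10 epithelial markers, 6 fell and none rose (the same adjusted over the list alone), with a median of -0.80 (camera adjusted p = 0.00218; adjusted p = 0.199 with an estimated correlation). The simple epithelial keratins KRT8, KRT18 and KRT19 were 1.75-fold, 1.73-fold and 2.10-fold lower than the 1501 ± 47.3, 854 ± 7.47 and 343 ± 11.3 CPM of untreated cells (SD, n = 3). KRT7, CLDN4 and CLDN7 also fell, and the epithelial adhesion gene EPCAM, at 1.44 ± 0.253 CPM in untreated cells (SD, n = 3), did not pass (0.06, adjusted p = 0.882). Of 19 heat shock genes, 12 fell and 2 rose (13 and 2 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.0259; adjusted p = 0.213 with an estimated correlation). The chaperones HSPD1, FKBP4 and HSP90AB1 fell by 0.32, 0.29 and 0.26. The stress-inducible HSPA1A and HSPA1B, nearly identical genes whose reads may be shared, rose by 0.24 and 0.33.

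**Figure D2:**
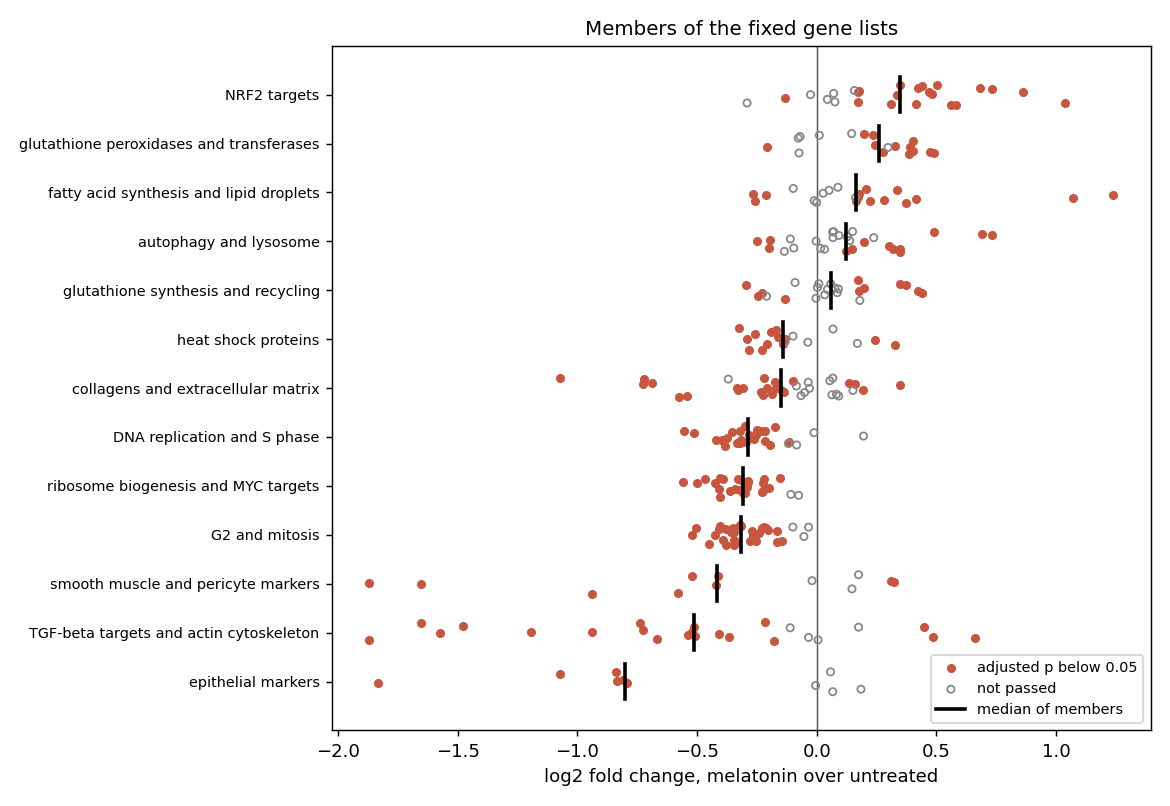
Log2 fold change, melatonin over untreated, of each measured member of the 12 lists that passed camera and of the glutathione synthesis list, 1 point per gene, filled where the adjusted p was below 0.05. Black bars mark list medians, from -0.80 for epithelial markers to 0.35 for NRF2 targets.

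Among the genes with the largest changes, the oxytocin receptor gene OXTR fell from 58.3 ± 2.24 to 11.4 ± 0.806 CPM (SD, n = 3; log2 fold change -2.36 ± 0.07 SE, adjusted p = 2.26e-15). FST, an activin-binding protein, was 6.56-fold lower, and SH2D5, KRT80, TENM2, MARCH4, GFRA1 and LPPR4 had log2 fold changes of -1.99 to -2.70. CD274, which encodes the immune checkpoint ligand PD-L1, fell from 7.20 ± 0.376 to 1.82 ± 0.355 CPM (SD, n = 3; adjusted p = 4.29e-09). The genes that rose most included ID4 (1.58), the NADPH oxidase DUOX2 (1.53), the fatty acid carrier FABP4 (1.49), the immediate early gene EGR1 (1.40), the lysosomal transporter SLC46A3 (1.35) and the sterol reductase TM7SF2 (1.26). The same rule named a pair of read-through symbols that overlap other genes, so their counts are uncertain. JMJD7-PLA2G4B rose by 2.03 ± 0.21 (SE), while JMJD7 (-0.02, adjusted p = 0.915) and PLA2G4B (-0.37, adjusted p = 0.0594) did not pass. RTEL1-TNFRSF6B rose by 1.26 ± 0.44 (SE; adjusted p = 0.0309), with 0 counts in untreated library 2. That call ended without untreated library 1 (adjusted p = 0.0592) or melatonin library 3 (0.154), after thinning (0.0547) and in DESeq2 (0.613), within a range over alternatives of 3.16e-13 to 0.613, and its log2 fold change was 0.68 without untreated library 2 and 2.12 without untreated library 3.

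**Figure D3:**
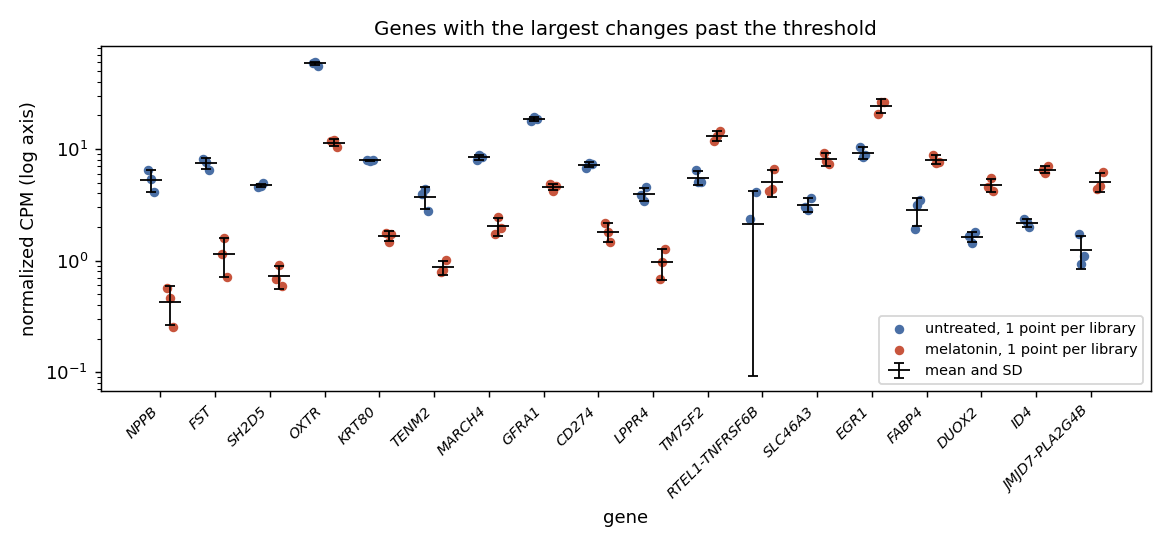
Normalized CPM on a log axis for the 10 genes with the largest fall and 8 of the 10 with the largest rise past the threshold, 1 point per library, with the mean and SD of 3 untreated and 3 melatonin libraries. OXTR lay near 58.3 CPM in untreated cells and near 11.4 CPM with melatonin, and RTEL1-TNFRSF6B had 0 counts in untreated library 2, which the log axis leaves out.

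Of the other fixed lists, the immunomodulatory and trophic factors of mesenchymal stem cells moved in both directions, with 7 of 23 higher and 10 lower (adjusted p = 0.0959). PDCD1LG2, the gene of PD-L2, fell with CD274, from 11.4 ± 1.42 to 3.13 ± 0.212 CPM (SD, n = 3), and ANGPT1, VEGFC, FGF2 and VEGFA also fell, while GDNF, KITLG, STC1, TGFB1 and IL6 were among those that rose. Among chemokine receptor, migration and homing genes 4 of 18 rose, including ACKR3 and TIMP1, and 8 fell, including S1PR1 and AXL (adjusted p = 0.053). That list passed without untreated library 2 (adjusted p = 0.0286) or melatonin library 3 (0.0461), within a range over fits with the preset correlation of 0.0159 to 0.157. Of 26 NF-κB and inflammatory cytokine genes, 10 rose, among them CXCL1, CXCL2, CXCL3, CCL20 and IL1B, and 4 fell, among them IL11 (adjusted p = 0.131). In glycolysis 3 of 22 rose and 9 fell, including SLC2A1, HK2 and PFKP (adjusted p = 0.053). Hypoxia targets had 5 of 24 higher and 5 lower (adjusted p = 0.887), the nuclear-encoded respiratory chain 1 of 36 and 4 (0.841), and mitochondrial biogenesis and dynamics 2 of 20 and 6 (0.585). In the circadian clock list 2 of 20 rose, PER1 and NPAS2, and 8 fell, among them PER2, PER3, NR1D2, ARNTL and CLOCK (adjusted p = 0.252).

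Stress and signalling lists that did not pass are given as members higher and lower. Integrated stress response genes had 3 of 36 higher and 13 lower (adjusted p = 0.152), endoplasmic reticulum chaperones 3 of 25 and 8 (0.831), metallothioneins and zinc 1 of 12 and 1 (0.823), and ferroptosis and iron 6 of 16 and 5 (0.585). Aryl hydrocarbon receptor targets had 5 of 13 higher and 4 lower (adjusted p = 0.841), CREB and cAMP targets 7 of 19 and 5 (0.514), immediate early genes 8 of 24 and 9 (0.717), interferon-stimulated genes 6 of 22 and 2 (0.841), and Wnt and Notch genes 4 of 20 and 7 (0.548). Cholesterol biosynthesis genes had 6 of 24 higher and 3 lower (adjusted p = 0.585), p53 targets 4 of 25 and 6 (0.981), apoptosis regulators 3 of 20 and 2 (0.847), senescence genes 5 of 18 and 6 (0.841), and replication-dependent histones 2 of 15 and 0 (0.717), where the 2 calls, HIST2H2BE and HIST1H2BC, did not pass without melatonin library 3 (0.0672 and 0.0652), with log2 fold changes of 0.70 and 0.97 with it and 0.55 and 0.79 without it. For the lists that did not pass, counts adjusted over the list alone were the same except for the mesenchymal surface markers, glycolysis (3 and 13), the immunomodulatory factors (7 and 12), Wnt and Notch genes (5 and 8) and immediate early genes (8 and 10). For the immediate early, endoplasmic reticulum, interferon, hypoxia and p53 lists the median, the mean and the direction of the test differed in sign.

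Markers of cell identity were measured beside these groups. Mesenchymal stem cell surface markers had 3 of 18 higher and 7 lower (4 and 8 adjusted over the list alone; adjusted p = 0.235), with CD44, ALCAM, MCAM and THY1 among those that fell and NT5E (-0.05) and ENG (-0.07) not passing. Besides the epithelial and smooth muscle markers, lists of other cell types did not pass. Pluripotent markers had 0 of 7 higher and 2 lower (adjusted p = 0.578), endothelial markers 2 of 5 and 3 (0.841), osteoblast markers 0 of 6 and 4 (0.193), adipocyte markers 2 of 8 and 1 (0.585), chondrocyte markers 1 of 9 and 2 (0.841, with a median of 0.13 against a test direction of lower), and neural markers 1 of 6 and 1 (0.981). Of the haematopoietic markers, the tested members CD68 (0.18) and CD74 (0.71) did not pass and were too few for a list test.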

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

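Thinning to equal depth and the GC and length correction were chosen after the result was seen; the other alternatives were fixed before the data were examined. No named gene or list past the threshold changed direction under any alternative, and no gene called both in the planned analysis and in an alternative changed sign. Some that did not pass did change direction, among them the CREB, interferon, senescence, aryl hydrocarbon receptor and neural lists, higher by camera and lower by fry, none past the threshold in either. Some settings moved a count of genes by over 1.5 times. With total counts only, 3440 genes were higher and 1739 lower (2197 and 2568 with TMM), which turned the balance of calls, after a median shift of 0.07 on the log2 scale. With at least 10 counts in every library, 155 genes instead of 254 changed at least 2-fold, since fewer low-count genes were tested. With the number in the library names as a replicate block, 1345 genes were higher and 1766 lower. The title number as a replicate block gave 2027 higher and 2404 lower. Libraries sharing a title number did not deviate together (correlations of -0.06, 0.03 and -0.04), nor did those sharing a library-name number (0.01 and -0.02). With the title block the smooth muscle list did not pass (adjusted p = 0.0737, median -0.42); no other named gene or list changed its call.

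For lists, camera with an estimated correlation called 0 higher and 0 lower, and fry called 8 higher and 17 lower. Leaving out 1 library gave 1631 to 2481 genes higher, 2038 to 2824 lower, 234 to 282 changed at least 2-fold, 4 to 4 lists higher and 7 to 9 lower. DESeq2 called 1752 higher and 2235 lower and kept 83.6% of the calls. Limma-voom kept 98.8%, median-of-ratios scaling 99.2%, no filter 97.2% and thinning 91.4%. The GC and length correction kept 97.6% and called 5501 genes, against 4765 in the planned analysis. Fewer calls were kept with total counts only (82.6%) and with the library-name block (63.3%). Leaving out 1 library kept 75.2% (without melatonin library 3) to 92.5% (without melatonin library 1). Without a filter 335 genes changed at least 2-fold. The migration and immunomodulatory lists and TXNRD1 passed with total counts only (0.0386, 0.0347 and 0.0209), where SLC7A11 did not (0.286). Glycolysis and the migration list passed without a filter (0.0221 and 0.0159) and with the GC and length correction (0.0437 and 0.0436). GCLM (0.0541), GSR (0.0862), NFE2L2 (0.254), SLC7A11 (0.264) and the heat shock list (0.0672) did not pass with the library-name block. The log2 fold changes of these genes there were 0.18, 0.15, 0.11 and -0.10, and the list median was -0.15. In that fit untreated library 1 and melatonin library 3 each stood alone in a block, so neither informed the melatonin difference. The comparison thus rested on fewer libraries, which weakens its calls and lowers its counts of genes. Depth limits low genes: 3 counts are 0.123 to 0.161 CPM.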

Other observations

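The tests of read-through symbols and of PPAR, YAP and TAZ, and BMP targets were chosen after the result was seen. The settings of thinning and of GC and length correction were added after the data were examined. The tests that use these settings, and the tests not named here as chosen afterwards, were written before the results they measure were seen.

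Several list members not described above also changed, and they were chosen after their values were seen. Among 20 regulators of apoptosis, of which 15 did not pass, the pro-apoptotic BCL2L11 rose from 2.95 ± 0.159 to 6.41 ± 0.242 CPM and the anti-apoptotic BCL2L1 fell from 55.1 ± 1.09 to 35.6 ± 0.872 CPM (SD, n = 3). The pro-apoptotic PMAIP1 fell by 0.25, and BMF and CASP9 rose. AP-1 subunits moved apart, with FOS (0.85) and JUNB (0.56) higher and FOSL1 (-0.96) and JUN (-0.20) lower. Among antioxidant enzymes, TXNRD2, the mitochondrial thioredoxin reductase, fell from 2.02 ± 0.123 to 0.615 ± 0.245 CPM and SESN3 rose from 2.03 ± 0.458 to 4.33 ± 0.23 CPM (SD, n = 3). The iron exporter SLC40A1 rose from 0.775 ± 0.161 to 1.94 ± 0.509 CPM, while TFRC, the transferrin receptor, fell by 0.15.

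Splitting the 6 libraries into groups of 3 can be done in 10 ways, too few for a share under 0.05. The real split gave 2197 genes higher, 2568 lower and 254 changed at least 2-fold, and the highest of the other splits gave 0 in each case, so 1 of the 10 splits reached each count. For lists the real split gave 4 higher, which 3 of the 10 splits reached (highest other 4), and 8 lower, which 1 split reached (highest other 6). Each of the other splits sets 2 libraries of 1 condition with 1 of the other against the reverse. This puts the difference between conditions inside both groups, which widens their spread and makes calls of genes unlikely. Their 0 calls of genes are therefore no measure of chance. Part of the difference between conditions also remains between the groups of such splits, and the source of their list calls was not tested.

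The joint fall of mitosis, DNA replication and ribosome biogenesis genes was weighed against technical explanations. Over the 90 members the median log2 fold change was -0.30, with quartiles of -0.38 and -0.22. Removing per-library GC and length trends left -0.31, so these trends did not account for the whole fall. Thinning to equal depth left -0.30, but it does not change the expected fold of well-counted genes, so it cannot decide. The scaling nearest to 0, total counts only, left -0.24. It moves all genes by nearly the same amount (median shift 0.07), so the choice between TMM and total counts did not account for the whole fall. A lower share of dividing cells or a lower output per cell with melatonin may underlie the fall, and neither was tested. These could not be separated here, since no cell number or cycle phase was measured in these libraries.

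A second pattern concerned 9 symbols that had 0 counts in some libraries and at least 50 in others, out of 11905 symbols that reached 50. Read-through symbols made up 66.7% of them and 0.303% of the others (Fisher's exact test, two-sided, p = 1.11e-13). For 0% of them did the zeros lie in all libraries of 1 group and none of the other. With 9 symbols and 10% given by chance this is an ordinary outcome, so it does not decide on melatonin treatment as the cause. Most had their 0 in a single library, while FAM72D had 0 in every melatonin library and in untreated library 2. The near-identical EIF3C and EIF3CL exchanged zeros while their sum stayed at 29 to 47 counts, and RPL21 had 0 counts in melatonin library 2 and 332 to 508 elsewhere. The counting may have assigned shared reads to 1 of several overlapping symbols per library, and the call of RTEL1-TNFRSF6B, the only one of the 9 past the threshold, could come from that. JMJD7-PLA2G4B was not among the 9, and its rise stays open.

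In melatonin library 3, RMRP had 749 counts (31.7 CPM) and RPPH1 had 145 (6.13 CPM), against 86 and 161 and 29 and 38 counts in the other melatonin libraries. These are RNAs without a poly(A) tail. A further 58 RNAs were taken by symbol as lacking a tail, histone RNAs included, and this was not checked for each. Over these the median log2 ratio of that library to the mean of the other melatonin libraries was 0.76, and 53 were higher. That library may hold more RNA without a poly(A) tail, and whether this arose in cells or in library preparation was not tested. RMRP rose by 1.18 with melatonin (adjusted p = 0.0311) but had -0.09 without that library (adjusted p = 0.793). RPPH1 went from 1.40 to 0.46 without it (adjusted p = 0.288). The histone genes HIST2H2BE and HIST1H2BC went from 0.70 to 0.55 and from 0.97 to 0.79 and did not pass without it (adjusted p = 0.0672 and 0.0652), which leaves open how much of their difference that library carries.

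The rise of genes including PDK4, ANGPTL4 and FABP4 prompted the hypothesis that targets of PPAR nuclear receptors rise with melatonin. Over 27 targets that had not prompted it, 12 rose and 2 fell, with a median of 0.17 (camera adjusted p = 0.00475 over 3 such lists; adjusted p = 0.293 with an estimated correlation). The median lay at the 99.99th percentile of 10000 random lists of the same size and expression. Members of random lists were drawn independently, while the estimated correlation within the PPAR list was 0.14, so the percentile takes no account of correlated members. Fixed lists also hold 7 of these members, among them PLIN2, so the counts and the percentile are not separate from the list results above. The remaining 20 members had a median of 0.17 (camera adjusted p = 0.0112). No percentile was computed for them. Among enzymes of fatty acid oxidation in this list, CPT2, ACADVL, ACAA1 and EHHADH rose, ECI2 fell by 0.26, and ACAA2, HADHA, HADHB, ACADM and DECR1 did not pass. The shift of the list may reflect PPAR activity, a hypothesis found and tested in the same libraries.

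The fall of ANKRD1, CYR61 and AXL prompted a like hypothesis for targets of YAP and TAZ, coactivators that respond to cell tension. Over 14 other targets, 8 fell and 1, IGFBP3, rose, with a median of -0.30 (camera adjusted p = 7.35e-04; adjusted p = 0.17 with an estimated correlation). The median lay below all 10000 random lists, which again take no account of correlated members (estimated correlation 0.09). Here too 5 members are also in fixed lists, so their values are not separate from the list results above. The remaining 9 had a median of -0.31 (camera adjusted p = 0.00559). Lower YAP and TAZ activity may thus accompany the lower contractile genes, again from the same data. The third hypothesis, that BMP targets rise beyond ID1 and ID4, did not pass. Over 13 other targets 4 rose and 3 fell, with a median of 0.24 (camera adjusted p = 0.0982; adjusted p = 0.308 with an estimated correlation), at the 98.5th percentile of random lists. The 4 that rose include ID2 and ID3, and without the 6 members that fixed lists also hold the adjusted p was 0.388.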
